A study of Rattus norvegicus with 48 samples.

How the data were processed

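RNA was extracted with TRIzol from liver, kept above a RIN limit, and made into polyA libraries with the Illumina TruSeq RNA v2 kit, per the labels' protocols. Each of the 48 rats (6 LH, 6 LN and 36 F2, all male) gave 1 library. The submitters' processing notes name TopHat 1.4.1, Cufflinks 2.0.0 and the rat genome build rn4. The annotation release, read length, strand setting and any scaling between libraries are not given in the sources used here. The authors deposited 1 table of FPKM (fragments scaled to gene length and to the mapped fragments of the library) with a column per rat, whose names equal the sample titles, and all columns were matched to a sample by that title, leaving 0 unmatched. FPKM has the library's mapped total divided out, so a rise in a few abundant genes lowers all others, and reads shared by near-identical genes are split by the authors' estimate.

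The identifiers are Ensembl gene IDs, and 0 of the 29516 were found in the gene table used here. Gene symbols, positions and sequence context are therefore not reported. The 34 gene lists of liver metabolism, immunity and cell types that had been fixed before the data were examined, a regression on the study's candidate gene RGD1562963 in F2 rats, and a test of neighbouring genes needed symbols or positions and were not run, so composition by cell type was not checked. The rule for named genes also asked for a symbol. Without it, the 2 highest and 2 lowest log2 differences among genes past the threshold with no overlap between strains are named.

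Values were analysed as log2(FPKM + 1), for the 10183 genes with a mean of at least 1 FPKM over the 48 libraries. Differences were tested in R 4.3.3 with limma 3.58.1 (linear models, empirical Bayes with a mean-variance trend, two-sided tests, Benjamini-Hochberg adjustment, threshold 0.05). The LH against LN test used the 12 parental libraries alone, because F2 rats segregate both genomes and vary more. F2 rats were compared with the mean of the LH and LN means in a model of all 48 libraries. Variability was tested with limma on absolute deviations from the group mean, corrected for group size. The position of F2 was the F2 mean minus the LN mean, divided by the LH minus LN difference. The leading F2 axis was the first singular vector of centred F2 values over the 10134 genes left after 49 genes listed at 0 in some library and above 100 FPKM in another were set aside. In a file without counts such a 0 can be a failed estimate. However, 40 of the 49 genes were at 0 in 40 or more libraries, so for most of them the high value was the rare one.

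Depth is unknown in FPKM. For genes with values under 0.1 FPKM in a library and in LH replicate 1, the log2 ratios pile up where both hold the same small number of fragments, and the mode of at least 601 ratios gave the relative depth. A median of 34.2% of ratios lay within 0.1 of the mode, and 2.81% in F2 rat 20, so the estimate is approximate. No counting interval was derived from it. Samples of 36 F2 and 6 rats per strain limit the precision, and standard errors are given with the differences.

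The steps were tested on simulated values with the real means and within-strain spreads of 10134 genes and 200 changed genes. The strain test recovered 58.0% of genes changed by 0.5 on the log2 scale and 90.0% of those changed by 1, and 4.40% of its calls were unchanged genes. The position estimate gave 0.51 for genes simulated midway, and the excess variance gave 0.94 of the simulated locus. The midparent test called 0 genes when none was off the midparent and 95.0% of those shifted by 0.5. The F2 rats were simulated with the within-strain spread and independent noise. Their real variance was a median of 2.47 times as large, with 35.6% of it on 1 axis. The rates for F2 may therefore not carry over to the real comparisons.

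The alternatives planned at the start were a pseudocount of 0.1, no filter or a minimum mean of 5 FPKM, median-of-ratios and quantile scaling, robust empirical Bayes, a spread from all libraries or by group, a replicate block, an exact rank-sum test, leaving out each parental rat, deviations from medians and removal of the first component. The F2 position, the excess variance, the matched lists, the pairwise correlations in F2, the axis covariate, quantile scaling of the midparent comparison and the removal of libraries or genes with values of 0 were added after the data were seen. Figures were drawn with matplotlib 3.10.9.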

Results

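Liver polyA RNA was measured in 48 male rats of 3 groups. The Lyon Hypertensive strain (LH) is an inbred rat selected for high blood pressure that also has raised body weight and plasma lipids, and the Lyon Normotensive strain (LN) is its normotensive companion strain. There were 6 LH rats, 6 LN rats and 36 F2 rats, each with its own library, so the replicates were separate animals. The labels give the cross only as F2, and the study is known to have intercrossed LH and LN. The series asks which genetic differences underlie the metabolic syndrome of LH. The deposited values were FPKM for 29516 Ensembl rat gene identifiers, of which 9826 were at 0 in every library and 10183 had a mean of at least 1 FPKM and entered the comparisons. Neither the file nor the gene table used here pairs these identifiers with gene symbols or with positions, so genes are given by identifier and described in groups by their behaviour.

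FPKM carries no read totals, and the absolute depth of each library is unknown. The spacing of the lowest values gave an approximate relative depth, set to 1 at the median library. Relative depth was 0.844 ± 0.044 in LH (SD, n = 6), 1.08 ± 0.18 in LN (SD, n = 6) and 0.997 ± 0.131 in F2 (SD, n = 36), and the shallowest library, at 0.689, was an F2 rat. The number of genes above 0 was 15180 ± 107 in LH (SD, n = 6), 15551 ± 290 in LN (SD, n = 6) and 15319 ± 288 in F2 (SD, n = 36). No libraries were identical, and the most similar of all library pairs had a correlation of 0.986 across genes. The 50 most abundant genes took 49.9% ± 1.6 of the summed FPKM in LH (SD, n = 6), 48.2% ± 1.8 in LN (SD, n = 6) and 52.3% ± 3.2 in F2 (SD, n = 36).

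The first comparison asked which liver genes differ between the hypertensive and the normotensive strain. Of the 10183 genes, 315 (3.09%) differed, 115 of them higher and 200 lower in LH than in LN (limma moderated test on log2(FPKM + 1), two-sided, Benjamini-Hochberg adjusted p under 0.05). The differences were mostly modest. The median absolute difference of the 315 genes was 0.60 on the log2 scale, a 1.51-fold change, with a median standard error of 0.11 and quartiles of 0.45 and 0.86. A group of 54 genes differed by at least 2-fold, 30 higher and 24 lower in LH. The count changed with single rats of either strain. With LH replicates 1 to 6 left out in turn it was 194, 205, 391, 169, 217 and 194. With LN replicates left out in the same order it was 222, 238, 211, 250, 359 and 384. In 232 of the 315 genes the 6 LH values and the 6 LN values did not overlap. Over all genes tested, 326 (3.2%) showed no overlap, against 0.216% by chance for 6 against 6. By mean expression, 180 of the strain-different genes lay under 10 FPKM, 109 between 10 and 100 FPKM and 26 at 100 FPKM or more. These counts were not set against all genes tested.

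The balance of directions depended on how the libraries were scaled. With the values as deposited, 36.5% of the calls were higher in LH and the median log2 difference of all genes was -0.09. After median-of-ratios scaling that median was -0.03, and 253 genes were called, 147 higher and 106 lower in LH (58.1% higher). Quantile normalization gave 149 higher and 106 lower. Of the 315 genes, 221 were called again with median-of-ratios scaling, and 50 of the 54 genes with 2-fold differences were called under either scaling.

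Among the 232 called genes without overlap between the strains, the 2 with the largest log2 difference in each direction were as follows. ENSRNOG00000029262 was at 30.6 ± 2.4 FPKM in LH (SD, n = 6) and 3.56 ± 1.77 FPKM in LN (SD, n = 6). Its log2 difference was 2.86 (SE 0.19, limma adjusted p = 3.49e-06). ENSRNOG00000031412 was at 7.94 ± 1.57 FPKM in LH (SD, n = 6) against 0.234 ± 0.192 FPKM in LN (SD, n = 6), a log2 difference of 2.85 (SE 0.13, limma adjusted p = 9.87e-08). ENSRNOG00000030636 went the other way, at 3.82 ± 1.13 FPKM in LH (SD, n = 6) and 55.3 ± 19 FPKM in LN (SD, n = 6), a log2 difference of -3.50 (SE 0.23, limma adjusted p = 3.49e-06). ENSRNOG00000018121 was at 1.08 ± 0.70 FPKM in LH (SD, n = 6) and 11.2 ± 2.5 FPKM in LN (SD, n = 6), a log2 difference of -2.60 (SE 0.21, limma adjusted p = 1.72e-05). These differences are on the log2(FPKM + 1) scale, which understates the change of low genes.

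For each of the same 4 genes the F2 values reached from the values of 1 strain into those of the other. ENSRNOG00000029262 ran from 1.56 to 61.9 FPKM in F2 and ENSRNOG00000031412 from 0 to 15.5 FPKM, beyond the highest LH values of 33.3 and 10.6 FPKM. These 2 genes are not separate examples. The F2 rats under 1 FPKM in ENSRNOG00000031412 were the lowest in ENSRNOG00000029262, at up to 7.93 FPKM, and the next rat had 15.5 FPKM. ENSRNOG00000030636 ran from 2.43 to 49.1 FPKM and ENSRNOG00000018121 from 0.863 to 19.2 FPKM, where the highest LN values were 74.4 and 15.7 FPKM. On the log2 scale the F2 variance of ENSRNOG00000031412 was 34.2 times the within-strain variance, and the ratios of ENSRNOG00000029262, ENSRNOG00000030636 and ENSRNOG00000018121 were 12.7, 5.30 and 5.50.

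**Figure D1:**
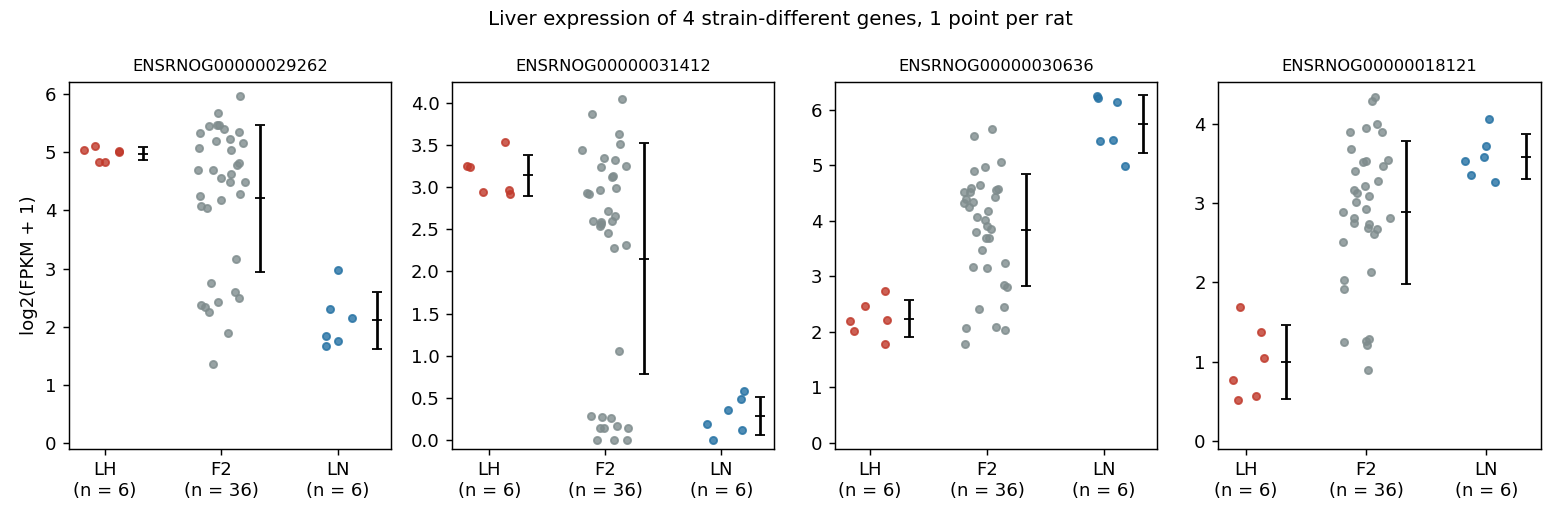
Expression of the 2 genes with the largest log2 difference in each direction, among called genes without overlap between the strains, as log2(FPKM + 1) on the vertical axis, in LH, F2 and LN rats (1 point per rat; the bar is the mean with 1 SD). The 36 F2 rats reach into the values of both strains, with ENSRNOG00000031412 running from 0 to 15.5 FPKM.

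A set of 4 genes stayed under 1 FPKM in all 6 rats of 1 strain and above 3 FPKM in all 6 rats of the other, limits set after the values were seen. All 4 were high in LH, with LH means between 4.49 and 7.94 FPKM and LN means between 0.227 and 0.391 FPKM. In 3 of them 10 of the 36 F2 rats lay under 1 FPKM (27.8%, exact 95% binomial interval 14.2% to 45.2%). In the other one, 12 of 36 did (33.3%, exact 95% interval 18.6% to 51.0%). The genes are not independent, since a pair of them shared 9 of these rats, while 24 rats lay under 1 FPKM in at least 1 of the 4 and 1 rat in all 4. The intervals cover the sampling of rats only.

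The second comparison asked where the F2 rats lie relative to their parents. For the 54 genes with 2-fold strain differences the F2 mean lay close to the middle as a median over genes, but not for every gene. On a scale where 0 is the LN mean and 1 the LH mean, their median position was 0.51 (quartiles 0.44 and 0.69, 95% bootstrap interval of the median over genes 0.46 to 0.57). For 41 of the 54 genes the position was from 0.25 to 0.75, and single genes ran from -0.08 to 0.91. The F2 mean was between the strain means for 53 of these 54 genes and for 263 (83.5%) of all 315. The median position was 0.52 for the 30 genes higher in LH and 0.51 for the 24 genes lower in LH. Genes are not independent replicates, so these intervals describe the spread over genes.

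**Figure D2:**
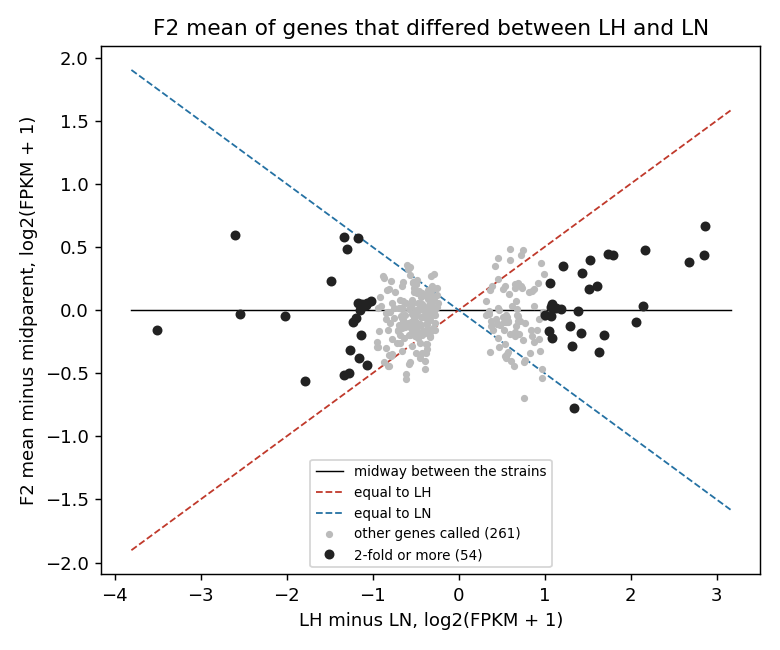
F2 mean minus the mean of the LH and LN means (vertical axis) against the LH minus LN difference (horizontal axis), both in log2(FPKM + 1), for the 315 genes that differed between the strains. Dashed lines mark an F2 mean equal to LH or to LN, and 53 of the 54 genes with a 2-fold difference (black) fall between them.

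Across all genes, the F2 rats differed from the midparent, the mean of the LH and LN means, at 2302 genes, 732 higher and 1570 lower in F2 (limma, adjusted p under 0.05). The differences were small, with a median absolute log2 difference of 0.38, a 1.30-fold change, and a median standard error of 0.12, and 26 genes reached 2-fold. Of the 315 strain-different genes, 43 (13.7%) were called off the midparent, and of the other genes 22.9% were. With quantile normalization the split was 1289 higher and 1205 lower. Against single strains, 109 genes differed between F2 and LH and 841 between F2 and LN.

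The difference from the midparent ran along the direction in which F2 libraries varied among themselves. The leading axis of variation among F2 rats took 35.6% of their variance. Set to 0 at the midparent, the score on this axis was 23.1 ± 24 in F2 (SD, n = 36), 3.53 ± 5.94 in LH (SD, n = 6) and -3.53 ± 11.21 in LN (SD, n = 6). The mean score of the F2 rats lay above that of the 12 parental rats (2-sided permutation p = 0.00215). The sign of the axis was chosen so that its gene weights correlated positively with the F2 minus midparent difference. The direction of this shift is therefore not a result. Single rats overlapped, at -10.6 to 92.4 in F2, -6.39 to 11.7 in LH and -17.8 to 12.4 in LN. The sum of FPKM was 692716 ± 50566 in F2 (SD, n = 36), 623985 ± 12955 in LH (SD, n = 6) and 623630 ± 27807 in LN (SD, n = 6). Among the 36 F2 libraries the score rose with the sum of FPKM, with Pearson's r of 0.79 and Spearman's rho of 0.81 (2-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give, and 4e-05 after adjustment over 4 relations). Without the 2 libraries farthest from the median sum, r was 0.82. The score fell with the number of genes above 0, with r of -0.66 (permutation p = 2e-05, adjusted 4e-05) and rho of -0.56 (p = 0.00033, adjusted 0.00066), and r was -0.57 without the 2 farthest libraries. With the axis score as a covariate no gene was called off the midparent by limma. In that fit 732 had an unadjusted p under 0.05, against 509 expected by chance. The score itself differs between F2 and the strains, so the covariate takes up part of the group difference. The 0 calls therefore do not show that no difference remains. The count of calls also changed with the libraries kept. Without 12 F2 libraries and LN replicate 5, which list an abundant gene at 0, limma called 20 genes, 4 higher and 16 lower. Still, 3199 had an unadjusted p under 0.05, against 3947 with all libraries. In comparison, 100 removals of LN replicate 5 with 12 random F2 libraries gave a median of 2487 calls and a range of 14 to 4201. Only 1 of these 100 removals gave 20 calls or fewer. The axis score averaged 32.4 (SD 25.8) in the 12 F2 libraries listing 0 and 18.5 (SD 22.1) in the other F2 libraries. The labels give no batch or date, so a batch that differs between F2 and the strains cannot be told apart from the group.

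**Figure D3:**
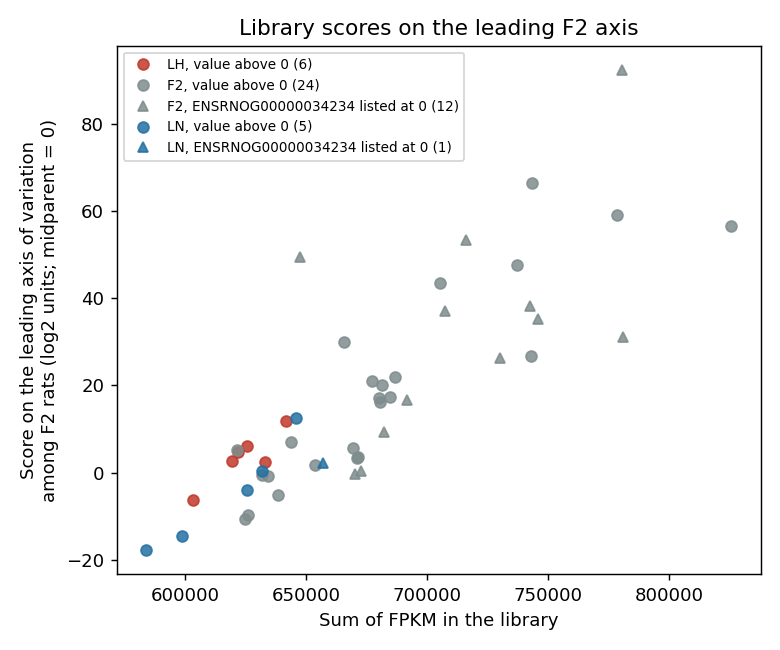
Score of each library on the leading axis of variation among F2 rats (vertical axis, log2 units, midparent at 0) against the sum of FPKM in the library (horizontal axis), by group, with triangles for the 13 libraries that list ENSRNOG00000034234 at 0. F2 scores averaged 23.1, with an SD of 24, against 3.53 in LH and -3.53 in LN.

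The third comparison asked whether genes vary more among F2 rats, in which the parental alleles segregate, than within the inbred strains. The F2 variance exceeded the pooled within-strain variance for 92.8% of genes, with a median ratio of 2.47. The F2 libraries were also more dispersed in the median-of-ratios size factor. Its SD was 0.079 in F2 (n = 36), 0.030 in LH (n = 6) and 0.014 in LN (n = 6) (2-sided permutation p = 0.00095, 0.0038 adjusted over 4 library measures). The adjusted permutation p was 0.0271 for the spread of the upper quartile of FPKM, which was larger in F2. For relative depth it was 0.543, with a larger SD in LN (0.181) than in F2 (0.131). For the score on the leading F2 axis it was 0.0142. That axis is by definition the direction in which the F2 rats vary most. A larger F2 spread on it was largely fixed in advance and is not counted here. Strain-different genes varied more than others in F2. Their median ratio was 3.53 against 2.45 for the remaining genes, and the 54 genes with 2-fold differences had a median of 2.82 (quartiles 1.85 and 5.51), with F2 above the strains for 52 of them. Because the strain test favours genes with a small within-strain variance, the 315 genes were also set against 10000 random lists matched on mean expression and on within-strain variance. Their median F2 variance was 0.136 (log2 units squared), against a median of 0.099 and a highest value of 0.115 over the lists. With the leading F2 axis removed, the values were 0.104, 0.064 and 0.074, and the median ratio of F2 to within-strain variance fell to 1.59 over all genes.

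An additive locus that carries the whole strain difference adds one-eighth of the squared difference to the F2 variance. For the 54 genes the F2 variance in excess of the within-strain variance was a median of 0.98 times that amount (quartiles 0.69 and 1.47, 95% bootstrap interval over genes 0.81 to 1.17). Over all 315 strain-different genes it was 1.96. When the median F2 variance of matched genes without a strain difference was subtracted in place of the within-strain variance, the median was 0.65 (quartiles 0.26 and 1.22). Of the 54 genes, 7 lay under 0.25 and 6 above 2 in the first of these.

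**Figure D4:**
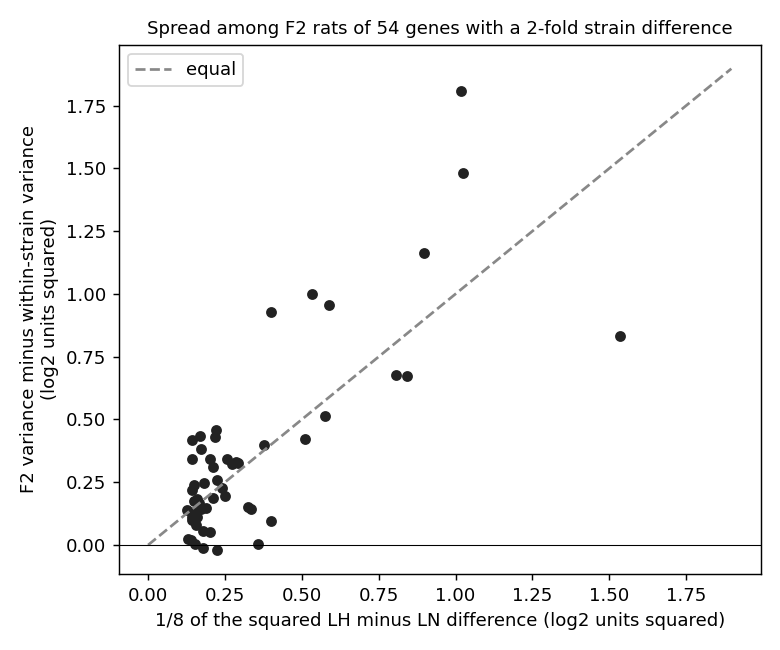
F2 variance minus pooled within-strain variance (vertical axis) against 1/8 of the squared LH minus LN difference (horizontal axis), both in squared log2 units, for the 54 genes with a 2-fold strain difference (1 point per gene; the dashed line marks equal values). The points scatter about the line, with a median ratio of 0.98, against 1.96 over all 315 strain-different genes. The median for the 54 genes was 0.74 without the first F2 component. It was 0.65 with the F2 variance of matched genes without a strain difference subtracted instead.

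Gene by gene, the spread test made few calls. A limma test on absolute deviations called 7 genes, 1 more and 6 less variable in F2. All 7 were among the 49 genes listed at 0 in some library and above 100 FPKM in another. Of those 49, 40 were at 0 in 40 or more libraries. At an unadjusted p under 0.05, 2945 genes were more variable and 34 less variable in F2. All 7 lay outside the 315 strain-different genes, and with 1 gene called more variable the shares of strain-different and other genes called could not be compared. On simulated data this test recovered 23% of genes given an additive locus and a log2 difference of 2 or 3.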

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

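Groups of 6 parental rats were searched for a single rat far from the rest in 32 group and measure combinations, and 4 stood apart, where chance gives about 1 in 20. These tests were set up after the library measures and gene values had been seen.

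LN replicate 5 accounted for 3 of the 4. It had 6.91 FPKM of ENSRNOG00000029262 against 3.94 FPKM in the next LN rat, 27044 FPKM of ENSRNOG00000031979 against 17737 FPKM in the next, and 0 FPKM of ENSRNOG00000034234 where the other 5 LN rats had at least 16775 FPKM. The remaining one was LH replicate 3, with 6.50 FPKM of ENSRNOG00000019704, one of the 4 genes near silent in LN, against 4.24 FPKM in the next LH rat.

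The 0 in LN replicate 5 belongs to a wider pattern. ENSRNOG00000034234, with a median of 17723 FPKM, is listed at 0 in 13 libraries, 12 of them F2, and nowhere between 0 and 12976 FPKM. An allele without the transcript is argued against by the inbred LN strain itself, in which 1 rat lists 0 and 5 list high values. A candidate explanation is that the estimate failed at high abundance, since ENSRNOG00000031979, a gene of similar level, ran from 27044 to 39048 FPKM in 10 of the libraries listing 0 and was itself at 0 in the other 3. All 10 exceeded the highest value of the 35 libraries that list ENSRNOG00000034234, 26509 FPKM (exact permutation p = 3.13e-10 for this order, chosen after the values were seen). Reads moved between the 2 genes stay open as a further explanation. They would also raise the partner gene where the other is at 0, so this order does not tell the 2 explanations apart. Where it was listed, ENSRNOG00000034234 itself reached 30128 FPKM.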

How the results depend on the processing

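The axis covariate, quantile scaling of the midparent comparison, the removals of genes or libraries with a 0, and all alternatives to the F2 position, the excess variance and the correlated pairs were chosen after the results were seen. The strain count of 315 stayed within 1.5 times under 7 other settings of pseudocount, filter, scaling, robust fitting, the axis covariate and the removal of genes listed at 0 (250 to 330 genes). It was 190 with a minimum mean of 5 FPKM, which tests fewer genes, 95 with the spread of all 48 libraries, which includes the F2 rats, and 54 with a 2-fold minimum. The exact rank-sum test called 0 (1715 at an unadjusted p under 0.05), since its smallest p gives an adjusted p of 0.0676. With the replicate block the count was 160, of which 145 were among the 315, and 43 of the 54 genes with 2-fold differences were called. The labels do not say that the numbers pair animals, same-numbered libraries deviated from their group means with correlations of -0.11 to 0.15, and 1 of the 6 LH libraries correlated best with the LN library of its own number. Leaving out 1 rat gave 169 to 391 genes, with more than a 1.5-fold loss without LH replicate 1 (194), 2 (205), 4 (169) or 6 (194), the cause of which was not tested. The 4 named genes kept their direction in 91 of 91 alternative values and the threshold in 87, all but the rank-sum test. The midparent count of 2302 was 1243 with a minimum of 5 FPKM (639 higher and 604 lower), 4100 with a spread per group, 109 against LH alone, 841 against LN alone, 0 with the axis score as a covariate (limma, 732 at an unadjusted p under 0.05) and 20 without the 13 libraries listing ENSRNOG00000034234 at 0 (3199 at an unadjusted p under 0.05, against 3947 with all). The spread test's 7 calls became 777 without a filter on low values (300 more and 477 less variable), 4 with a minimum of 5 FPKM, 0 with deviations from medians (2545 at an unadjusted p under 0.05) and 0 without genes listed at 0 (2985 at an unadjusted p under 0.05). The cause was not tested for these. The median F2 position stayed between 0.51 and 0.52 in all 4 alternatives run. The excess variance of 0.98 was 1.13 on the linear scale, 0.91 with median-of-ratios scaling, 0.74 without the first F2 component, 0.65 over a matched baseline and 1.96 over all 315 genes, without a test of the cause. The share of correlated pairs in the predicted direction, 95.9%, was 80.1% with no component removed, 77.9% at r over 0.5, 100% at r over 0.8 (39 pairs) and 97.9% with 10 components removed. Tests of neighbouring genes, of gene lists and of RGD1562963 were not run, for want of symbols and positions. Depth could not be turned into counts, so low genes have no counting error.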

Other observations

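Apart from the chance counts, the depth test without its interval, the comparison with dominance and the lists of uncalled genes, the tests in this part were chosen after the result was seen. Some strain-different genes moved together in F2 rats, in about as many pairs as other genes did. After the 3 leading components of the F2 libraries were removed, 123 of 49455 pairs among the 315 genes had an absolute correlation over 0.7 across the 36 rats, against a median of 104 and at most 212 pairs in 100 lists of uncalled genes of the same mean expression. These pairs linked 115 genes into 30 groups, the largest of 42 genes and the next of 7. Of the pairs, 97 were positive and 26 negative.

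The hypothesis concerns the direction of these correlations, not their number, and is that such groups carry strain alleles of linked or shared loci that segregate together, which predicts a positive correlation where LH differs from LN the same way in both genes and a negative one where it differs in opposite ways. The signs come from the parental rats and the correlations from the F2 rats. The prediction held for 95.9% of the 123 pairs, 96 of the 97 positive and 22 of the 26 negative ones. It held for no more than 72.4% over 10000 shuffles of the strain signs (permutation p = 1e-04, the smallest they can give). The shuffles treat genes as independent, while 115 genes fell into 30 groups, the largest of 42. Genes that move together can also share a strain sign by moving together among the parental rats. This p-value therefore overstates the evidence for the hypothesis. Variation along the 10 leading components of the F2 libraries is argued against as the whole source, because with these removed 97.9% of 94 pairs went the predicted way. Shuffles with the same limit gave at most 74.5%. Linkage, a shared regulator and other library-wide variation stay open: positions were not used here, and the share of 59.5% in 100 lists of uncalled genes (up to 73.5% within their central 95%) decides nothing, since 66.4% of uncalled genes had the same strain sign in replicates 1 to 3 and 4 to 6, against 100% of the 315.

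The F2 rats lay off the midparent at 2302 genes. Across 10134 genes, which are not independent replicates, the F2 minus midparent difference correlated with the gene weights of the leading F2 axis at r = 0.86. The positive sign of r was set with the axis, and only its size is a result. The shift is therefore consistent with more weight on one axis that already varies among F2 rats. Sequencing depth stays open, with r = -0.16 (95% interval -0.46 to 0.18) between relative depth and axis score over the 36 F2 libraries (permutation p = 0.361, adjusted 0.361, and rho = -0.20, p = 0.239, adjusted 0.239, with r = -0.02 without the 2 farthest libraries) but r = -0.66 for the number of genes above 0, and a permutation p of 0.448 for relative depth in F2 against both strains. Dominance was not tested by the count of shared calls. Of the 2302 calls, 43 were strain-different genes, but only 315 genes were called between the strains, which capped that number in advance. Of the strain-different genes 13.7% were called, against 26.3% in lists matched on expression and F2 variance (central 95% range 21.9% to 31.1%). Those lists do not test dominance, because genes of high F2 variance can owe it to the leading axis, along which the midparent difference runs. Dominance therefore stays open, with 4 of the 54 genes with 2-fold differences called off the midparent. A library batch, the state of the animals and the mixed F2 genome stay open and cannot be told apart from the group.

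Regrouping the libraries at random bears on the 3 counts. The strains called 315 genes and the highest of the other splits of the 12 parental libraries called 5, so 1 of 100 splits, the real one, gave as many. For the midparent count of 2302, 1 of 100 regroupings gave as many, and the highest other gave 1197. Chance can be excluded at 0.05 for these 2 counts. Regrouping does not separate strain from a batch or depth difference between the LH and LN libraries. Mean relative depth was 0.844 in LH and 1.08 in LN, and the mean size factor 0.983 and 1.04. For genes more variable in F2 the real grouping called 1 and the others 0, so 1 of 100 gave as many, but that gene is among those listed at 0 and without them limma called 0 (2985 at an unadjusted p under 0.05), so nothing follows about chance.

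In the 4 genes near silent in LN, the shares of F2 rats under 1 FPKM, 10, 10, 12 and 10 of 36, were not shown to differ from the 1 in 4 LN homozygotes of a single locus (exact binomial p = 0.701 for 3 of them and 0.251 for the other), and these are not 4 separate tests, since a pair of the genes shared 9 of the rats. The rows of the deposited table are ordered in part by strain difference, with 304 of the 315 genes above row 3506, the first row at 0 in every library.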
